A study of Mus musculus with 4 samples.

How the data were processed

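Gene expression was measured on 4 Affymetrix mouse arrays, which carry 45101 probe sets, each a group of short oligonucleotides read together as 1 value for a transcript. Per the labels, all 4 arrays carried target made from total RNA of mouse brain, hindbrain and spinal cord. On 2 arrays the hybridised target was cDNA amplified with a Nugen kit, and on the other 2 it was antisense RNA (aRNA) from T7-based amplification. Within each preparation the arrays carry the numbers 0 and 1. The labels do not say what the numbers stand for, from how many animals the RNA came, or whether the 2 preparations used the same RNA.

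The deposited values are intensity on a linear scale, 1 per probe set and array, with no detection call. The software that summarised the probes into probe sets is not given in the sources used here. The 2% trimmed mean of the values was 2500.02 on each of the 4 arrays, so the authors' deposited intensity values were already scaled to a common mean, and they were kept as they stand under a rule fixed beforehand. Scaling of this kind sets the arrays to an equal mean brightness, so a difference in total signal between the preparations cannot be seen in them. The number of arrays, 2 per preparation, limits the precision of every comparison. The labels do not say whether the arrays came from separate animals, and aRNA array 0 differed from the other arrays in sex-linked transcripts. Each p-value therefore measures only the spread between these arrays. That spread may be technical, and between the aRNA arrays it may also come from unlike RNA.

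Values were taken as log2(intensity + 16). A fold on this scale understates the change of dim probe sets. The 64 control probe sets were left out of the tests, and of the other 45037 the 22519 whose mean over the 4 arrays was at or above the median (8.38 on the log2 scale) were tested. Signal over background was judged from 27 control probe sets for Bacillus transcripts: the 95th percentile of their intensity was 212 and 247 on cDNA arrays 0 and 1, and 123 and 126 on aRNA arrays 0 and 1. Where an array on the lower side lay under that level, the fold of a named gene is given as a lower bound against it (the higher of the level and the probe set's own value on each array).

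Gene names came from the platform annotation supplied with the value table, which lists 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Probe sets with several symbols were not named. Symbols were updated through gene identifiers in a RefSeq gene table, in which 34741 of the probe sets with 1 symbol (99.4%) were found; the other 204 kept the annotation's symbol. Tested probe sets with 1 symbol covered 11945 genes. No genome coordinates are given.

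The preparations were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjustment over the probe sets tested, threshold 0.05), cDNA against aRNA with 2 residual degrees of freedom. The numbers were compared in an additive model with preparation and number, which leaves 1 residual degree of freedom. For gene lists, 1 probe set per gene was kept, the one with the highest mean over the arrays, and limma's camera was run with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The groups, tests, 34 gene lists and most alternatives were fixed before the data were examined; the tests of the lists between the numbers were added afterwards. Of the 34 lists, 29 had at least 3 measured members and were tested. Correlations and spreads between arrays are descriptive, and probe sets are not independent replicates. The tests of explanations in the closing part were revised up to 3 times after their results had been seen, so they are exploratory. The first versions argued against 7 of 9 explanations. Those that used genes or probe sets picked by the outcome, or levels under background as if measured, were replaced. Camera with an estimated correlation was used for 3 of them for a time and dropped, since no list passes it with so few arrays. The 11 tests given here argue against 6 explanations, 3 of them worded more narrowly than at first, and leave 5 open; sex of the RNA source was split by preparation after a rule that asked for Y-linked signal on both cDNA arrays proved wrong, and RNA of the other sex on 1 array had been read as met and is now open. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

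Named genes followed a fixed rule. For the preparations they are the 12 probe sets with the largest difference in each direction among those past the threshold with a single gene symbol, a name not ending in _x_at and both cDNA arrays on the same side of both aRNA arrays, 1 per gene, and up to 4 members of each list that camera called. The ranking used the values as they stand, also under background, so it is not a ranking of the bounds. For the numbers they are up to 8 per direction with the same sign in both preparations. Genes named outside the rule were chosen after their values were seen, and are marked so in the text; this also holds for the sex-linked genes.

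Both models were tested on simulated data before use, with 20 data sets of 22519 probe sets, 200 of them changed. The comparison of preparations recovered 2.6% of simulated 2-fold changes, 44% of 4-fold, 80% of 8-fold and 94.5% of 16-fold changes, and 5.27% of its calls were false. In the real comparison 43.2% of the tested probe sets were called, far more than were changed here, so these rates need not describe it. The simulated noise was drawn for each probe set independently. The comparison of numbers recovered 13%, 64.6%, 93.7% and 98.7%, but its 1 residual degree of freedom gave a median of 16 false calls per data set and up to 91, 16.3% of all its calls. Alternatives covered the normalization between arrays, the pseudocount, the filter on dim probe sets, the intensity trend, probe sets prone to cross-hybridisation, each array left out, the number as a block, the set test and the choice of probe set per gene.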

Results

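Transcript levels of mouse brain, hindbrain and spinal cord were measured on 4 arrays, 2 hybridised with cDNA target (Nugen kit amplification) and 2 with aRNA target (T7-based amplification). Each pair holds an array numbered 0 and an array numbered 1. The median intensity was 372 and 386 on the cDNA arrays and 338 and 342 on the aRNA arrays, at an equal 2% trimmed mean. Of the 22519 probe sets tested, 2.32% and 3.65% lay under the background level on cDNA arrays 0 and 1, and 1.16% and 1.2% on aRNA arrays 0 and 1. Below, differences are on the log2 scale, and mean values carry the SD over the 2 arrays of a preparation.

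The sex-linked transcripts did not follow the preparation. Xist, the RNA that coats the inactive X chromosome and is made in female cells, was high at its probe set 1436936_s_at on cDNA array 0 (11.94), cDNA array 1 (12.51) and aRNA array 1 (15.44), and low on aRNA array 0 (8.55), which was the lowest array at all 3 Xist probe sets. Eif2s3y, a translation factor gene on the Y chromosome, gave 13.12 on aRNA array 0 against 7.92 and 4.75 on cDNA arrays 0 and 1 and 6.79 on aRNA array 1. This gene lay outside the probe sets tested. Any comparison of the preparations therefore also sets arrays with unlike sex-linked transcripts against each other, and so does the difference between the 2 aRNA arrays.

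The first question was how alike the arrays of one preparation were, and how alike the preparations. Across the 22519 probe sets, Pearson's r was 0.941 between the 2 cDNA arrays and 0.957 between the 2 aRNA arrays. Between the preparations the mean over the 4 pairs was 0.723 ± 0.0077 (SD of 4 pairs), with Spearman's rho of 0.935, 0.957 and 0.713 in the same order. The median absolute difference between the arrays of a pair was 0.37 for cDNA and 0.33 for aRNA, against 0.88 between the means of the preparations. Among the dimmest 7507 probe sets it was 0.58 for cDNA and 0.43 for aRNA, and among the brightest 7506 it was 0.24 and 0.26.

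Genes of meninges and fibroblasts, of pericytes and smooth muscle, and GABAergic and glycinergic, glutamatergic and synaptic genes were higher on the cDNA arrays than on the aRNA arrays, by the counts and camera tests given below. The glutamatergic median did not stand out from random lists once all lists were counted (permutation p 0.321). Camera also called oxidative phosphorylation and proteasome genes lower, but with medians that random lists also gave. None of these calls between the preparations held with a correlation estimated from the data (adjusted p = 0.675 with an estimated correlation for each of the 7 lists), a test in which no list tested passed 0.05 unadjusted, and fry called none (13 at an unadjusted p under 0.05). Single probe sets of widely expressed genes differed in both directions. Ttr (transthyretin, the thyroid hormone carrier that choroid plexus secretes) had the largest fold, as measured or as a lower bound, among the genes named here. At its probe set 1451580_a_at it reached 16.14 ± 1.41 (SD, n = 2) on the cDNA arrays and lay under background on both aRNA arrays, at least 516-fold higher on cDNA (limma adjusted p = 1.43e-05). All 4 Ttr probe sets tested were called higher. Pcp2, a marker of cerebellar Purkinje cells named after its values were seen, was 13.23 ± 0.43 (SD, n = 2) on cDNA at probe set 1424944_at and lay under background on aRNA array 1, at least 52.7-fold higher on cDNA (limma adjusted p = 0.000196). Srd5a3, a polyprenol reductase, was at least 22.5-fold lower on the cDNA arrays, where it lay under background.

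In all, 4556 probe sets were called higher and 5166 lower on cDNA than on aRNA, and 12797 did not pass. At an unadjusted p under 0.05, 11545 passed. The difference was at least 2-fold for 4008 of those called higher and 4429 of those called lower. The median difference of all tested probe sets was −0.11, and −0.25 with each array centred on its median, so the smaller differences below are to be read against that shift. Higher calls made up 46.9% of the calls, or 39.5% with median centring.

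Further genes with the largest differences toward cDNA included Otud7a, a deubiquitinase gene, at least 208-fold higher, and Iqsec2, a guanine nucleotide exchange factor of synapses, at least 83.9-fold. Tagln, an actin-binding protein of smooth muscle, was at least 68.9-fold higher, and S100a9, a calcium-binding protein of neutrophils, at least 51.2-fold. E430024I08Rik (at least 161-fold), Tcta (at least 143-fold) and Tmem191c (at least 75.4-fold) also lay under background on both aRNA arrays. Miga2 (at least 222-fold) and Ptdss1 (a phosphatidylserine synthase, at least 291-fold) lay under it on aRNA array 0 and Rbm39 (a splicing factor, at least 276-fold) on aRNA array 1; Tmsb10, an actin-sequestering thymosin, was above it throughout and differed by 7.80. The adjusted p of these 12 genes lay between 4.34e-06 and 7.05e-05.

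Toward aRNA, Flywch1 and Zdhhc21 were at least 23.6-fold lower on cDNA, Lpcat1, a lysophosphatidylcholine acyltransferase, at least 34.9-fold, Csnk1e, a casein kinase, at least 11.4-fold and Slc35a5 at least 11.2-fold. Plcxd2 (at least 14.7-fold), Taok3 (at least 18.2-fold), Lrrc49 (at least 32.3-fold), the ubiquitin ligase Rnf6 (−5.16), the adaptor Crkl (−5.06) and the stress granule protein G3bp2 (−4.88) completed the 12. Plcxd2 and Taok3 lay under background on cDNA array 0, with adjusted p of 0.00245 and 0.00148, and Lrrc49 on cDNA array 1; the other 10 ran from 6.58e-06 to 0.000193.

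Probe sets of one gene often disagreed. Of 1688 genes with several called probe sets, 766 (45.4%) had called probe sets in opposite directions. As 46.9% of all calls were higher, calls that ignored the gene would also often disagree. In 1331 genes outside the lists weighed in the closing part, the kept probe set was called higher and others were tested. Those others had a median above 0 in 47.9% of these genes. A call at 1 probe set thus said little about the direction of a gene's other probe sets. Of the 12 tested probe sets of Rbm39, 5 were called higher and 2 lower, and of the 3 of Ptdss1, 1 was called each way. The 3 probe sets of Iqsec2 were all higher and both tested probe sets of Csnk1e lower. The fold or difference given above for each gene is that of 1 probe set. Tmsb10 was called at 1 of 4 tested probe sets (the others 0.68, 0.12 and 0.76). G3bp2 was called at 1 of 3 (the others −0.66 and 0.35) and Rnf6 at 1 of 2 (the other −0.38). Miga2 was called at 3 of 4, where the others called gave 2.21 and 2.06 and the 1 not called 0.02. Crkl was called at its only tested probe set, and those left out by the filter gave −2.72, 2.43 and −1.92. These rest on levels under background and have no firm size. The probe sets with −2.72 and −1.92 lay under it on both cDNA arrays, the last also on aRNA array 0. The probe set with 2.43 lay under it on both aRNA arrays.

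Among the lists called higher on cDNA, that of meninges and fibroblasts had the largest median, but not with the filter at the 75th percentile, where its median fell to 1.19 (adjusted p = 0.17), under those of pericytes and smooth muscle (1.61) and GABAergic genes (2.48), and no list was called. Of 14 measured genes of meninges and fibroblasts, 11 were called higher on cDNA, 1 lower and 2 neither, with the same counts adjusted over the list alone and a median difference of 3.0 (camera adjusted p = 0.000622). The transcription factor gene Foxc2, under background on aRNA array 1, was at least 45.2-fold higher; Col1a1, which encodes a collagen I chain, differed by 4.37, Foxc1 by 3.76 and the growth factor gene Igf2 by 3.67. Dcn, the proteoglycan decorin and the 1 member called lower (named after its values were seen), differed by −2.23. Of 10 pericyte and smooth muscle genes, 6 were higher and none lower, also over the list alone (median 1.98, camera adjusted p = 0.0319), among them Tagln (at least 68.9-fold), the smooth muscle myosin gene Myh11 (3.38), Myl9 (3.23) and the smooth muscle actin gene Acta2 (2.57).

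Neuronal groups with a call were also higher on cDNA. Of 8 GABAergic and glycinergic genes, 5 were higher and none lower (median 2.06, camera adjusted p = 0.0342), including the glutamate decarboxylase genes Gad1 (3.83) and Gad2 (3.41), Sst (somatostatin, 3.64) and Pvalb (parvalbumin, 2.48). Of 5 glutamatergic genes, 4 were higher (median 1.77, camera adjusted p = 0.0394; permutation p over all lists 0.321 against random lists): Neurod1 (4.03), Bcl11b (2.38), the vesicular glutamate transporter gene Slc17a6 (1.5) and Gria2 (1.13). The other tested Neurod1 probe set, 1426413_at, went the other way (−0.94, limma adjusted p = 0.517). Of 22 synaptic genes, 11 were higher and 1 lower (median 0.99, camera adjusted p = 0.0367), led by Cplx2 (3.93), Grin2b (3.47), Syn1 (2.78) and Camk2b (2.08). Counts adjusted over the list alone were the same for the first 2 lists, and 11 and 2 for the synaptic genes. Without an intensity trend, of the 7 lists only that of meninges and fibroblasts was called (adjusted p from 0.0595 to 0.071 for the other 6), and the glutamatergic call was also lost without the filter (0.0815). Some of these calls were lost with 1 array left out. Without aRNA array 1 the GABAergic list (adjusted p = 0.0562) and the glutamatergic list (0.0767) were no longer called, and without cDNA array 1 neither were the glutamatergic (0.0701) and synaptic lists (0.0788). Slc17a6 was not past the threshold without aRNA array 1 (0.64, adjusted p = 0.246), cDNA array 0 (0.0765) or cDNA array 1 (0.117), and Gria2 not without cDNA array 1 (0.052).

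Camera called genes of 2 housekeeping complexes lower on cDNA, but random lists of like mean level, drawn after the values were seen, gave medians as low: −0.35 to 0.19 for the first (permutation p over all lists 0.998) and −0.48 to 0.32 for the second (0.955). Of 77 nuclear genes of oxidative phosphorylation, 26 were lower and 7 higher (median −0.27, camera adjusted p = 0.0342), among them Ndufb1 (−2.43), Uqcr11 (−2.19), Uqcc3 (−2.0) and Ndufa1 (−2.0). Of 36 proteasome subunit genes, 15 were lower and 1 higher (median −0.42, camera adjusted p = 0.0393), among them Psmd11 (−1.70), Psmd7 (−1.48), Psmd13 (−1.38) and Psmc2 (−1.25). Counts adjusted over the list alone were 26 lower and 7 higher for the first list, and 15 and 2 for the second. The first call was lost without cDNA array 0 (adjusted p = 0.0522) or cDNA array 1 (0.0577), and the second without cDNA array 1 (0.0577) or aRNA array 0 (0.0831), where Psmd7 also did not pass (−1.24, adjusted p = 0.0881), or without probe sets named _x_at or _s_at (0.0816).

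The other 22 tested lists were not called, and their members named here were chosen after their values were seen. Cerebellum and hindbrain genes had 4 of 6 members higher, among them Cbln1 (4.38), and 1 lower, Meis1 (−2.37), with a median of 2.32 and camera adjusted p = 0.119 (0.0288 without cDNA array 0). Choroid plexus and ependyma genes had 3 of 5 higher, Ttr, Kcne2 (at least 14.3-fold, under background on both aRNA arrays) and Kcnj13 (at least 5.81-fold, under background on aRNA array 1), with a median of 2.97 (2.54 with levels under background raised to it) and adjusted p = 0.132 (0.0186 without cDNA array 0 and 0.0232 without aRNA array 0). Of 14 microglial and macrophage genes, 3 were higher and 1 lower (median 0.82, adjusted p = 0.29), but without aRNA array 1 the list was called (median 2.29, adjusted p = 0.00232). Mitochondrial ribosomal protein genes, 11 higher and 32 lower of 76 (median −0.42, adjusted p = 0.0576), were called without aRNA array 1 (adjusted p = 0.0303), and endothelial genes (median 0.99, adjusted p = 0.065) without cDNA array 1 (0.0161). Pan-neuronal genes had 6 higher and 3 lower of 22 (median −0.10, adjusted p = 0.644), motor neuron genes 2 and 2 of 7 (−0.19, adjusted p = 0.891) and monoaminergic and cholinergic genes 1 and 1 of 10 (0.20, adjusted p = 0.891). The medians were 0.05 for astrocytes and −0.08 for the oligodendrocyte lineage.

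**Figure D1:**
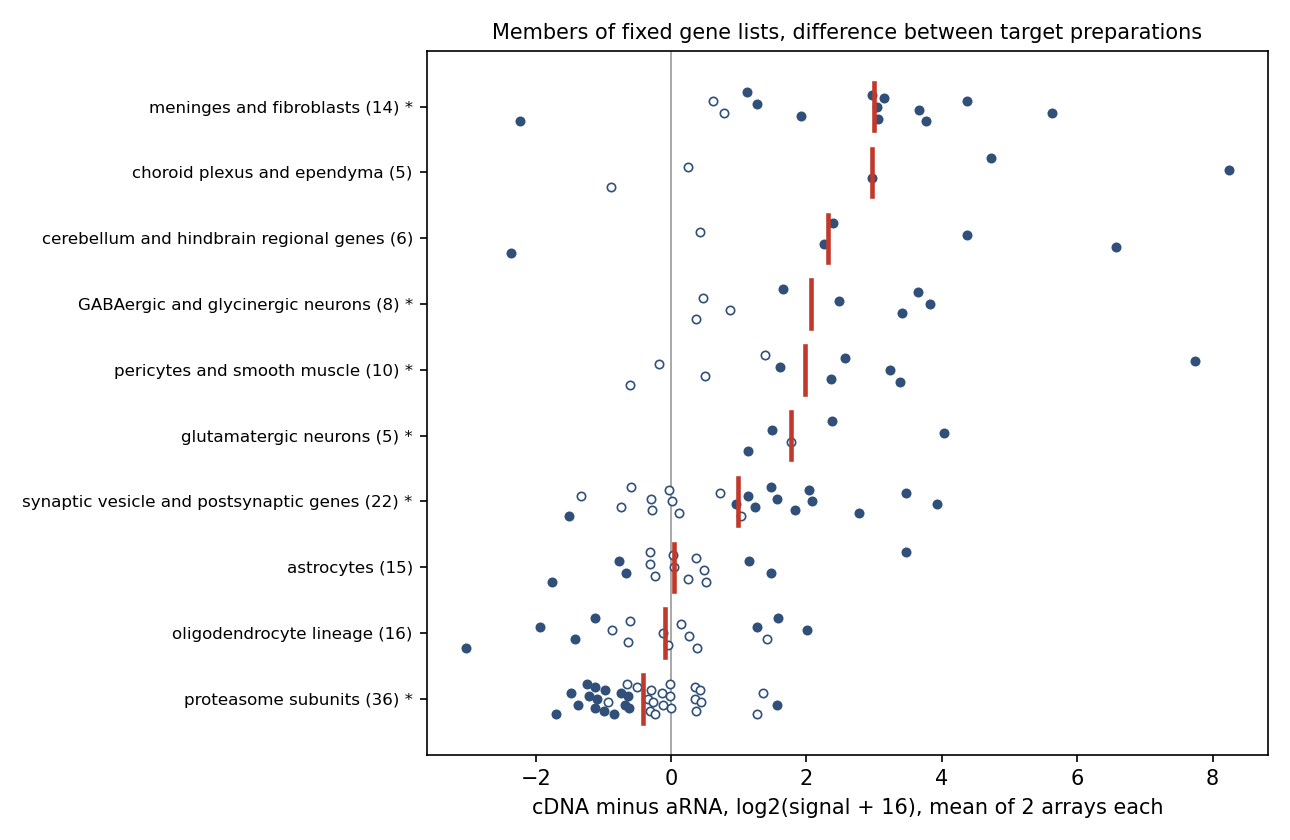
Each point is 1 gene of a fixed gene list (number of measured genes in brackets), placed by its cDNA minus aRNA difference on the horizontal axis in log2(signal + 16), means of 2 arrays each; filled points passed the adjusted threshold of 0.05, red lines are list medians and an asterisk marks lists that camera called. Only 10 of the 29 tested lists are drawn, and their medians run from −0.42 for proteasome subunits to 3.0 for meninges and fibroblasts.

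The 3' and 5' control probe sets of a transcript differ in affinity. The difference between them is therefore given for each preparation but read only as a contrast between the preparations. One target is cDNA and the other aRNA, so affinity may not cancel in that contrast either. The 3' minus 5' difference of Gapdh was 2.72 ± 0.94 on cDNA and 2.81 ± 0.58 on aRNA (SD, n = 2), and that of beta-actin 3.85 ± 0.32 and 3.45 ± 0.45. These differ by −0.09 and 0.40, against pooled SDs of 0.78 and 0.39. For pyruvate carboxylase it was 1.79 ± 0.06 on cDNA and 3.55 ± 0.19 on aRNA, 1.76 smaller on cDNA. For 18S ribosomal RNA, which carries no poly(A) tail, it was 2.90 ± 0.47 on cDNA and −0.53 ± 0.05 on aRNA, 3.43 larger on cDNA. The 18S probe set for the middle of the transcript read 16.80 on cDNA, above the 3' (11.86) and 5' (8.97) ones, and 13.86 on aRNA. The 18S contrast is therefore not a steady gradient along the transcript. The 5' probe set of the transferrin receptor lay under background on all 4 arrays, so its contrast, 2.05 larger on cDNA, has no firm size. With 2 arrays against 2, no exact two-sided permutation test can go below p = 0.333, and none was run. All 18 hybridization control probe sets, for spiked bacterial and phage transcripts, were higher on both cDNA arrays than on both aRNA arrays, by 2.19-fold to 6.99-fold with a median of 4.62-fold.

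The second comparison set the arrays numbered 1 against those numbered 0, which the labels do not explain. The median of the microglial genes was above 0 in both preparations, but 2 of the 14 passed the threshold over all probe sets (11 over the list alone) and the list call was lost with a correlation estimated from the data (adjusted p = 0.661 with an estimated correlation). Cst7 (cystatin F, a protease inhibitor of myeloid cells) lay under background on both number 0 arrays and was at least 13.1-fold higher on number 1 (limma adjusted p = 0.0175), at least 10.6-fold between the cDNA arrays and 16.4-fold between the aRNA arrays. Sprr1a, a small proline-rich protein gene, differed by 3.67 (adjusted p = 0.00902), and Gfap, the intermediate filament of astrocytes, was at least 7.95-fold higher at probe set 1426508_at (adjusted p = 0.034; under background on aRNA array 0). Prdx2, a peroxiredoxin gene, was lower by −3.04 at probe set 1430979_a_at (adjusted p = 0.00739), while its other probe set, 1418506_a_at, gave 0.16 between the cDNA arrays and 0.64 between the aRNA arrays.

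In total 14 probe sets were called between the numbers, 12 higher and 2 lower on number 1, and 1319 had an unadjusted p under 0.05. The other genes named by the rule were Mpeg1 (3.27, a macrophage perforin), the stress transcription factor Atf3 (2.96), Ly86 (2.80), the lectin gene Lgals3 (2.79) and Tyrobp (2.74, a receptor adaptor of myeloid cells). C1qa (2.70, complement) was named as a list member. Without an intensity trend in the variance none of these 10 genes passed (adjusted p = 0.924). The 4 calls outside the rule, named after their values were seen, were Gal (galanin, 1.97), Ctss (cathepsin S, 1.75), Rab3a at probe set 1459980_x_at (−2.55) and 1419004_s_at (at least 14.1-fold), which has several gene symbols and lay under background on aRNA array 0. The other Rab3a probe set, 1422589_at, gave 0.23 and 0.30 in the 2 preparations. The count rests on 1 residual degree of freedom. It was 62 with quantile normalization, 28 without the filter and 0 by limma without an intensity trend (1101 at an unadjusted p under 0.05). In the simulated data, with 200 probe sets changed, 16.3% of all calls were false, and the share among the calls here is not known.

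The differences between the numbers hardly went together across the whole transcriptome. Over the 22519 probe sets, Pearson's r between the cDNA difference and the aRNA difference was 0.041, Spearman's rho was 0.035, and 51.5% had the same sign. Differences of at least 2-fold coincided more often: 492 probe sets passed 2-fold in both preparations where 260 would by independence, 140 of them higher in both (62.6 by independence), 125 lower in both (66.1) and 227 opposite (131), an excess in every direction.

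Among the gene lists, tested between the numbers after the data had been seen, microglia and macrophages had the largest median. Of the 14 measured genes, 2 were called higher and none lower, or 11 and none adjusted over the list alone. The median difference was 1.71 (camera adjusted p = 3.66e-21), with a median of 1.13 between the cDNA arrays and 2.73 between the aRNA arrays, the pair whose Xist levels differ. The call was lost with a correlation estimated from the data (adjusted p = 0.661 with an estimated correlation). Tyrobp (2.74) and C1qa (2.70) passed the threshold over all probe sets, and Cd68 (2.88, adjusted p = 0.0613) and Laptm5 (2.2, adjusted p = 0.0588) did not; these last were named after their values were seen. Single members went the other way: Cx3cr1 by −0.68 and Mrc1 by −1.20 between the cDNA arrays, and P2ry12 by −0.21 between the aRNA arrays, also named after their values were seen.

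Of the other lists, 7 were called with smaller medians, at most 1 member past the threshold over all probe sets and at most 2 adjusted over the list alone. These were astrocytes (0.25), heat shock and immediate early genes (0.28, with Atf3), pan-neuronal genes (0.21), synaptic genes (0.24), replication-dependent histones (0.61), meninges and fibroblasts (−0.57) and the keratinocyte list kept as an outside control (1.24), in which Sprr1a was the member past the threshold. Against random lists of like level, drawn after the values were seen, the first 4 did not stand out in either pair (lowest permutation p over all lists 0.071, astrocytes, cDNA arrays). By the same p, meninges and fibroblasts stood out between the cDNA arrays only (0.0015, aRNA 0.957). Histones (0.0431, cDNA 0.637) and the keratinocyte list (0.0105, cDNA 0.0547) did so between the aRNA arrays only. None of the 7 held with a correlation estimated from the data either (adjusted p = 0.661 with an estimated correlation for each), and fry called none of the lists (3 at an unadjusted p under 0.05). The synaptic list was not called with quantile normalization (adjusted p = 0.0708), without the filter (0.056), with the 75th percentile filter (0.0774) or without an intensity trend (0.101), the histone list not without the filter (0.11, adjusted p = 0.606) or a trend (0.0503), and the pan-neuronal list not with quantile normalization (0.03, adjusted p = 0.294) or without a trend (0.0503). The oligodendrocyte lineage (0.08) and endothelium (−0.53) were not called.

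**Figure D2:**
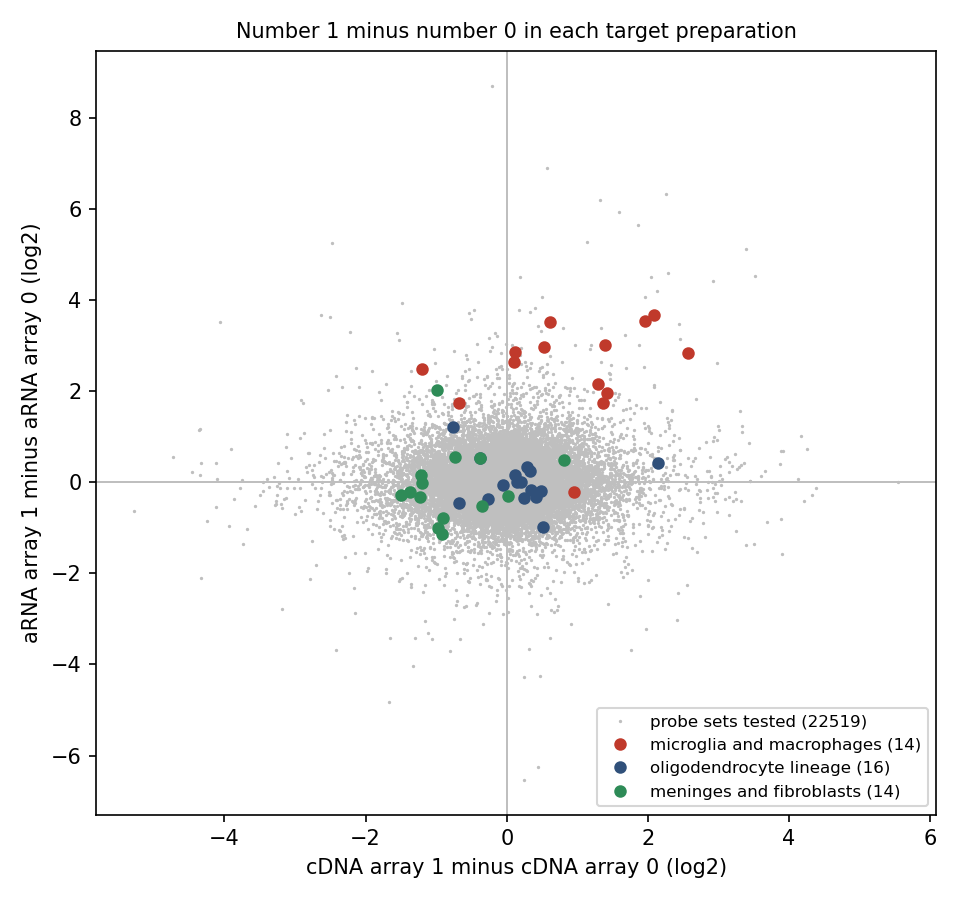
Each point is 1 of the 22519 probe sets tested, placed by the difference between the cDNA arrays numbered 1 and 0 (horizontal axis, log2) and between the aRNA arrays numbered 1 and 0 (vertical axis, log2); coloured points are the members of 3 gene lists. Of the 14 microglial genes, 12 lie above 0 on the cDNA axis and 13 on the aRNA axis.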

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

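The tests weighed here were all chosen after the values were seen. Among the probe sets left out by the filter on mean level, 5 stood out because 1 array lay at least 5 log2 units above each other array. The other arrays were under background there, except cDNA array 0 for Eif2s3y, so each gap between the values is given with its lower bound, levels under background raised to it. On aRNA array 0 these were Eif2s3y at probe set 1417210_at, 5.20 above the next array (at least 5.08), and the probe sets 1426438_at and 1426439_at, for which no gene is listed, 6.90 (at least 5.16) and 5.95 (at least 4.58) above. On cDNA array 1 they were Slc6a2, the noradrenaline transporter gene, at probe set 1460129_at, 6.69 above the next array (at least 4.59), and Dbh, which encodes the enzyme that makes noradrenaline, at probe set 1459848_x_at, 5.01 above (at least 3.89). The other 2 Dbh probe sets were also higher on cDNA array 1 than on cDNA array 0, by 2.35 and 2.33. Of the other 3 Slc6a2 probe sets, 1421641_at and 1442449_at were under background on both cDNA arrays and 1447311_at gave −0.18.

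The pattern on aRNA array 0 joins high Y-linked transcripts to low Xist. A loss of Xist during amplification would leave Y-linked genes at the level of the other arrays; with levels under background raised to it, 4 of the 9 probe sets of Eif2s3y, Uty and Kdm5d lay over 1 log2 unit above every other array, which argues against it (permutation p = 1e-04 against random probe sets of like level, the smallest that 10000 draws can give), while the median gap of the 9 was 0.14. A swap of the preparation label with a cDNA array is argued against by Pearson's r, which was higher by 0.239 with the other aRNA array than with the better of the cDNA arrays. RNA from an animal or pool of the other sex on that array may explain both. Xist lay 3.39 below the lowest other array at the probe set above background, 1436936_s_at, and at least 5.01 below at 1427262_at. At 1427263_at it lay at least 1.77 below, short of the 3 log2 units asked of each probe set. There aRNA array 1 read 8.89 and the background of aRNA array 0 was 7.11, so a bound of 3 could not be reached. The rule therefore cannot decide, and this explanation stays open. The arrays of a preparation, and those of a number, may therefore not hold RNA of the same animals.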

How the results depend on the processing

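The tests of gene lists between the numbers and their alternatives were added after the data were seen; the others were planned. The counts of 4556 higher and 5166 lower probe sets stayed within 1.5 times under every alternative run except the filter at the 75th percentile, which tests fewer probe sets and gave 2892 higher. Leaving out 1 array gave 3651 to 3902 higher and 3497 to 4700 lower. With the number as a replicate block the counts were 4788 and 5457 and 7 lists were called; the numbers are not shown to pair the samples (r = 0.041 of their differences over 2 pairs). List calls between the preparations fell from 7 to 0 with the 75th percentile filter (6 at an unadjusted p under 0.05), 1 without an intensity trend, 3 with the mean over probe sets of a gene, 0 with an estimated correlation (0 unadjusted) and 0 with fry (13 unadjusted), and were 4 to 8 with 1 array left out; the 4 came without cDNA array 1. The number count of 14 was 62 with quantile normalization, 8 with median centring, 9 with a pseudocount of 64, 28 without the filter, 7 without probe sets named _x_at or _s_at, 0 without an intensity trend (1101 unadjusted) and 0 without the preparation term (47 unadjusted); leaving out an array leaves no residual degree of freedom for it, so no such value is given. List calls between the numbers fell from 8 to 5 without a trend, 0 with an estimated correlation (0 unadjusted) and 0 with fry (3 unadjusted). The cause was not tested. Without the filter, r of the number differences was 0.014, and 0.059 with the 75th percentile filter; r within cDNA was 0.903 and 0.955, within aRNA 0.946 and 0.952, and between preparations 0.822 and 0.568; the spread within cDNA was 0.579 and 0.275, and within aRNA 0.443 and 0.275. With a pseudocount of 64 these were 0.945, 0.960 and 0.731 for r and 0.359 and 0.316 for the spread; with a pseudocount of 1, r within cDNA was 0.939 and within aRNA 0.954. Quantile normalization gave a spread of 0.320 within aRNA and a pyruvate carboxylase contrast of −1.56. No result past its threshold changed sign. Of the single genes named, 618 values under the alternatives kept their side of the threshold between the preparations and 8 did not, and 55 and 21 between the numbers. Signal over background limits the dim probe sets: 88 called higher lay under background on both aRNA arrays and 98 called lower on both cDNA arrays.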

Other observations

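The tests in this part were chosen after the values were seen. The 2 cDNA arrays differed from each other in genes of choroid plexus and meninges, a description of 2 arrays with no replicate to check it. Genes of choroid plexus and ependyma had a median 1.74 higher on cDNA array 1 than on cDNA array 0, and genes of meninges and fibroblasts one of −0.95; between the aRNA arrays the same lists gave −0.24 and −0.25. The fixed list of cerebellum and hindbrain genes had a median of 0.54 between the cDNA arrays, with Egr2 at −0.65. Single genes chosen after their values were seen were Gabra6, a granule cell GABA receptor subunit gene, at 3.02 (probe set 1417121_at), Neurod1 at 2.62 (1426412_at) and Cbln1 at 1.87 (1423286_at). Fmod, which encodes the matrix protein fibromodulin, was called higher on cDNA than on aRNA at all 6 of its probe sets and was lower on array 1 than on array 0 at each of them in both preparations, by −2.70 between the cDNA arrays at probe set 1438966_x_at (under background on aRNA array 1).

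Of the measured genes, 11 of 14 of meninges and fibroblasts, 6 of 10 of pericytes and smooth muscle, 3 of 5 of choroid plexus and 4 of 6 of cerebellum were called higher on the cDNA arrays; the last 2 lists were not called (camera adjusted p = 0.132 and 0.119). Preparation effects on single probe sets cannot be told apart: in 100% of the 8 genes with the list probe set called higher and other probe sets tested, those others had a median above 0, against 47.9% of 1331 other such genes (Fisher's exact test, two-sided p = 0.00283) and 50% of 986 with a difference of at least 1.12 (p = 0.00761), but 65.1% of 86 with at least 3.36, the median of the 8 (p = 0.0517), and 27 of the 35 genes lay outside this test. Preparation effects that fall on genes at random at a given level are argued against by 10000 random lists: the medians of 3.0, 1.98, 2.97 and 2.32 lay above the upper limits of 0.76, 0.97, 1.62 and 1.3 (largest permutation p of the 4, adjusted over all lists, 0.0238, or 0.0325 with levels under background raised to it), though such lists ignore any property that the genes of a list share. RNA with another regional or cellular make-up cannot be told apart from a preparation effect on these transcripts, because the labels do not say whether both preparations used the same RNA (median difference of the 35 genes 2.39).

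Microglial genes had a median above 0 between the numbers in both preparations. A lower share of neurons with all other cell types raised alike would raise their genes equally. The microglial genes exceeded those of oligodendrocytes, endothelium and meninges by 1.87 on average (1.69 over 14 genes against −0.17 over 40). The excess was 1.27 between the cDNA arrays and 2.46 between the aRNA arrays (pooled SD over genes 0.88 and 0.86), which argues against an equal rise. These 3 lists were chosen after the values were seen, and genes are not replicates. The astrocyte list, left out of this test, was also called higher with a median of 0.25, as was the pan-neuronal list (0.21). Noise that falls on genes at random is argued against by 10000 random lists of like level, whose medians ran from −0.42 to 0.28 and from −0.29 to 0.34 where the microglial ones were 1.13 (cDNA) and 2.73 (aRNA; permutation p adjusted over all lists 1e-04 in each, the smallest they can give). The sex of the RNA source is argued against between the cDNA arrays, where the microglial median was 1.13. Xist changed there by −0.21 to 0.57. Y-linked levels over background changed by at most 0.09, but 7 of the 9 Y-linked probe sets lay under background on both cDNA arrays. Those were raised to it, so their change was fixed in advance. The Y-linked values thus show a lack of clear signal on these arrays, not steady levels. Between the aRNA arrays, whose Xist differs, it cannot be told apart (2.73). A shift between single arrays shared by the genes of a list cannot be told apart either. Lists of other kinds also lay outside random lists in a single pair. Between the aRNA arrays these included GABAergic and glycinergic genes (median −0.92, permutation p over all lists 0.0051) and zinc finger genes (−0.18, permutation p 0.0022). Between the cDNA arrays they included choroid plexus genes (1.74, permutation p 0.0028) and meninges genes (−0.95, permutation p 0.0015). The outside control list of 4 genes lay outside random lists between the aRNA arrays (adjusted permutation p = 0.0105). Between the cDNA arrays it was near the threshold (0.0547, or 0.0407 with levels under background raised to it). In SDs of the random medians it lay 3.36 (cDNA) and 4.05 (aRNA) from their mean, against 6.75 and 16.7 for the microglial list. Its 4 genes passed the level filter and include Sprr1a, so it may not be free of tissue signal. A difference in the microglia themselves or in their number may remain; no biological explanation was tested, since the labels do not say what the numbers stand for.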
